A study of Mus musculus with 6 samples.

How the data were processed

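RNA was sequenced from spleen-derived CD8+ T cells of WT mice and of mice with hCD2-Cre and floxed Tcf7 and Lef1 alleles, after 72 h with IL-7 and IL-15, on a HiSeq-2000 per the labels. Groups were taken from the sample titles, with 3 samples each. The submitters' processing notes name FastQC, TopHat2 2.1.0 and Cuffdiff 2.2.1, and the genome builds mm10 and mm9 with no role. The annotation is not given in the sources used here.

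The authors deposited 1 Cuffdiff table of 23951 rows, with FPKM values per library as scaled in a pairwise run of the 2 groups at 72 h. They also deposited log2 fold changes, p-values and q-values of pairwise comparisons, which include groups at 0 h. Tests on the lists of called genes showed that all 603 genes listed for DKO against WT at 72 h, and no others, have q under 0.05, an absolute log2 fold change of at least 1 and at least 1 FPKM in the higher group. Per-library columns of 0 h groups, 6 in number, belong to no sample of this series and were not used. Columns of libraries carry the numbers 0 to 2 and the labels 1 to 3, so columns were assigned to a group and not to a numbered sample.

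Values were analysed here as log2(FPKM + 1), so a fold change understates the change of low genes. Genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, the group as the only term, two-sided, and Benjamini-Hochberg adjustment at 0.05. Count tests were not run because the values are not counts. Gene lists, 27 in number, were fixed before the data were examined, and the 22 with at least 5 measured members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. With the preset correlation 7 lists were lower and 2 higher, with an estimated correlation 0 and 0, and fry called 6 lower and 7 higher. The rule for named genes was also fixed then. It takes Tcf7 and Lef1, the 6 largest rises and 6 largest falls past the threshold with at least 5 FPKM in the higher group and groups that do not overlap, and from each list the 3 members with the smallest p. For the authors' comparisons it adds the 5 largest rises and falls among their calls with at least 5 FPKM.

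Overlaps of the authors' calls used Fisher's exact test across genes with at least 1 FPKM in a group of either comparison, in Python 3.11.15 with scipy 1.17.1. For genes with an infinite fall from 0 h to 72 h, the level at 0 h was not counted. Figures were drawn with matplotlib 3.10.9. For comparisons that share the WT 72 h libraries, unchanged groups were simulated 100 times with the spread of each gene within groups. Gene positions came from GENCODE M21 on GRCm38, to which 23582 rows matched by symbol. Transcript length and GC content for 1 check came from the same annotation.

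The test was run on simulated data of 10723 genes with 3 libraries per group. It recovered 32% of 50 genes changed by 0.5 on the log2 scale, 74% of those changed by 1, 100% of those changed by 2 and 96% of those changed by 3, and 6 of 157 calls were false. Simulated genes, also those of lists, were independent of each other, which real genes are not. These rates therefore do not cover deviations shared across genes, such as that of WT library 0 and DKO library 2. Relative depth came from the size of the smallest steps between low FPKM values compared with those of WT library 0. In the other 5 libraries 1648 to 1861 genes were compared, of which 14.5% to 18.9% gave a value within 0.02 of the most frequent ratio. Ribosomal protein genes took 23.1% to 34.4% of FPKM per library and small RNA rows 12.7% to 19.6%.

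Alternatives included other pseudocounts, filters, scalings and variance priors, a fold threshold, the column number as a replicate block, leaving out each library, and the authors' calls. Added after the data were examined were fits without small RNA rows, without WT library 0 and DKO library 2, with a term for these libraries, and with the level of Y-linked genes as a term, and camera with only its correlation or only its degrees of freedom changed.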

Results

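RNA was measured in mouse CD8+ T cells labelled as deficient in Tcf1 (encoded by Tcf7) and Lef1, a pair of related HMG-box transcription factors of T cells, and in wild-type (WT) cells. Naive CD8+ T cells, gated as GFP+ TCRbeta+ CD62Lhi CD44lo-med, were sorted from the spleen and cultured for 72 h with IL-7 and IL-15, cytokines that support T cell survival and homeostatic division. The series holds 3 libraries of WT cells and 3 of the cells labelled as deficient in both, called double-knockout (DKO) here, all at 72 h. Nothing in the labels says whether the 3 libraries of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may in part be technical. Xist and Y-linked RNA differed between libraries within both groups, so the 3 libraries of a group were not all technical repeats of 1 sample. Expression was deposited as FPKM (fragments scaled to transcript length and to the size of the library), so absolute depth is unknown. Steps between low values gave relative depths of 1.0 to 1.229 for WT and 1.1 to 1.187 for DKO libraries. Between 10473 and 10551 genes reached 1 FPKM in each library. Libraries are named by the column numbers 0 to 2 of the deposited table, which are not tied to the replicate numbers 1 to 3 of the labels.

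The targeted genes were lower in every DKO library. Tcf7 (chromosome 11, 52252371 to 52283014, minus strand) stood at 564, 555 and 532 FPKM in the WT libraries and at 288, 270 and 277 FPKM in the DKO libraries. Its log2 fold change was -0.98 (SE 0.092, limma adjusted p = 0.0041). Lef1 (chromosome 3, 131110471 to 131224356, plus strand) stood at 132, 105 and 157 FPKM in WT and at 48.5, 51.8 and 52.2 FPKM in DKO, a log2 fold change of -1.33 (SE 0.15, limma adjusted p = 0.0066). Positions are those of GENCODE M21 on GRCm38. Values per gene also count reads from exons that were not deleted, and the labels do not say which exon was floxed, so these values do not show whether either protein was absent.

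The first comparison asks how the labelled deficiency changed RNA in cells held for 72 h in IL-7 and IL-15. Gzma, Cdh1, Foxp3, St8sia6 and Fasl showed the largest rises and Dapl1, Ly6c2, Ppic and Gramd3 the largest falls on the log2(FPKM + 1) scale, small RNA genes aside. The order differs by the ratio of mean FPKM, where Gcnt4, a glycosyltransferase gene, rose 414-fold from 0.022 ± 0.0032 to 9.30 ± 0.35 FPKM, and AA467197 fell from 204 ± 74.1 to 24.2 ± 3.23 FPKM, 8.46-fold against 8.21-fold for Gramd3 and 7.47-fold for Ly6c2 (SD, n = 3 per group). For this comparison Gcnt4 and AA467197 fall outside the rule for named genes and were chosen after their values were seen. The rule admits them only for the authors' comparisons with 0 h groups. The fold of Gcnt4 rests on a WT mean of 0.022 FPKM, close to no signal. Gzma, which encodes the cytotoxic protease granzyme A, rose from 8.77 ± 6.20 to 458 ± 74.3 FPKM (SD, n = 3 per group). Foxp3, the lineage factor of regulatory T cells, rose from 3.69 ± 2.02 to 104 ± 10.2 FPKM, and Fasl, the death ligand of cytotoxic cells, from 3.28 ± 0.67 to 61.4 ± 6.86 FPKM. Cdh1, which encodes the adhesion protein E-cadherin, rose from 0.95 ± 0.54 to 49.6 ± 21.97 FPKM. St8sia6, a sialyltransferase gene, rose from 0.11 ± 0.11 to 18.3 ± 4.18 FPKM. Dapl1 fell from 129 ± 27.1 to 3.61 ± 1.27 FPKM, Gramd3 from 112 ± 12.7 to 13.6 ± 5.65 FPKM, and Ppic, which encodes cyclophilin C, from 21.0 ± 1.76 to 1.61 ± 0.37 FPKM. Ly6c2, which encodes the surface protein Ly6C, fell from 292 ± 118 to 39.1 ± 25.3 FPKM, with an adjusted p of 0.040. Reads of Ly6c2 can be shared with its close paralog Ly6c1, and its call was lost without WT library 0, 1 or 2 (adjusted p = 0.090, 0.12 and 0.084) and without DKO library 1 or 2 (adjusted p = 0.072 and 0.074).

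**Figure D1:**
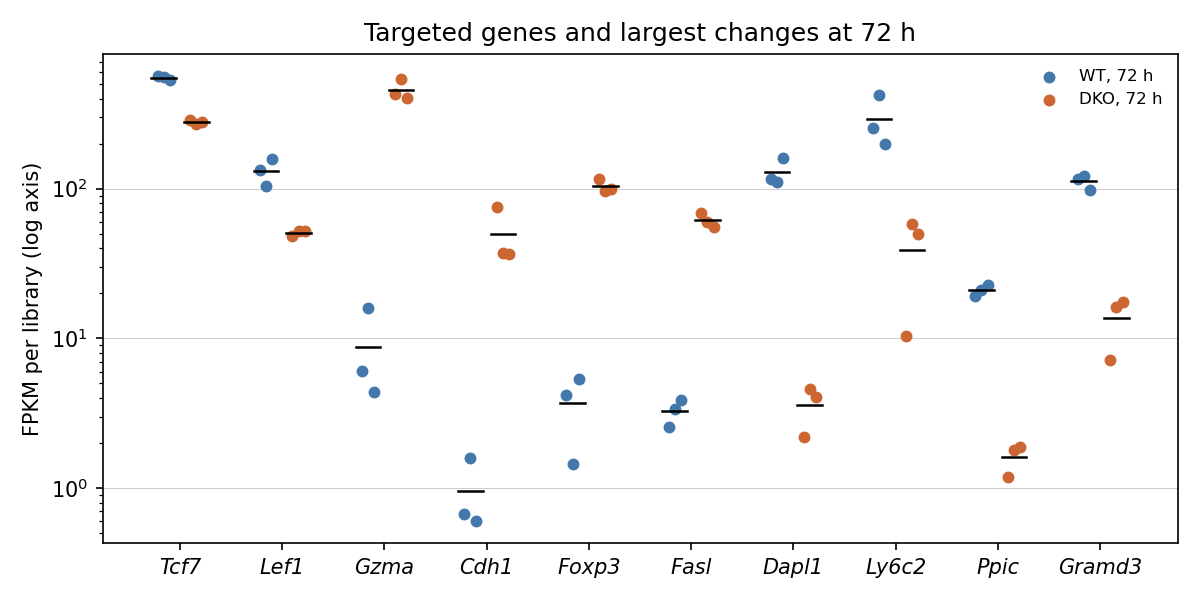
FPKM per library on a log axis for the targeted genes and for 8 of the genes with the largest changes, in WT (blue) and DKO (orange) cells at 72 h; points are the 3 libraries of a group and bars their mean. The groups do not overlap for any of these genes, and Gzma rises from a mean of 8.77 to 458 FPKM while Dapl1 falls from 129 to 3.61 FPKM.

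Of 10723 genes tested with limma on log2(FPKM + 1), 462 were higher and 682 lower in DKO cells at an adjusted p under 0.05, and 104 and 275 of these differed by at least 2-fold. The 3 libraries of one group lay apart from those of the other for 3654 genes, or 34.1%, where chance gives 10%. The authors' deposited table calls 179 genes higher and 424 lower, of which 130 and 325 were also called here, and 0 genes were called in opposite directions. The count was 630 without WT library 0, 663 without WT library 2, and 434, 388 and 500 without DKO libraries 0, 1 and 2. It was 28 genes without WT library 0 and DKO library 2, which deviated from their groups together. The rule for named genes also selected 3 small RNA genes listed at 0 in all libraries of one group. Mir1901 was listed at 0 in WT, and Snord45c and Mir6946 were listed at 0 in DKO. Values of small RNA rows scattered widely within groups, and 62 such rows with a mean of at least 50 FPKM in one group were listed at 0 throughout the other.

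Most measured genes of cell division were lower in DKO cells. The lists of G2/M and of S phase genes passed camera with a preset correlation, but neither did with an estimated correlation, where the adjusted p = 0.41 for each, and both passed fry (adjusted p = 0.0038 and 0.0064). Of 40 measured genes of G2/M and mitosis, 38 were lower and 0 higher (39 lower and 1 higher when adjusted over the list alone), with a median log2 fold change of -1.73. Bub1b, a kinase of the spindle checkpoint, fell from 26.2 ± 4.51 to 5.54 ± 0.28 FPKM (SD, n = 3), Bub1 from 7.42 ± 0.88 to 1.37 ± 0.22 FPKM, and Ccnb1, which encodes cyclin B1, from 16.8 ± 3.66 to 3.55 ± 0.26 FPKM. Of 46 genes of S phase and DNA replication, 39 were lower and 0 higher (44 and 0 when adjusted over the list alone), with a median of -0.88. Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, fell from 78.9 ± 15.4 to 16.1 ± 2.09 FPKM, and Uhrf1, which maintains DNA methylation after replication, from 66.8 ± 7.35 to 22.4 ± 1.996 FPKM. Among 4 measured histone genes, H2afx fell from 117 ± 32.3 to 48.5 ± 5.43 FPKM and Hist1h4i from 5.50 ± 0.98 to 1.99 ± 0.65 FPKM (2 lower when adjusted over the list alone). H2afx lost its call without WT library 2 (adjusted p = 0.05045) or DKO library 0, 1 or 2 (0.075, 0.057 and 0.065), and Hist1h4i without WT library 1 or 2 (0.069 and 0.072) or DKO library 1 or 2 (0.084 and 0.051). Members of the G2/M and S phase lists moved together between libraries, with estimated correlations of 0.69 and 0.66.

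Of 27 measured chromatin architecture genes, 8 were lower and 1 higher (9 and 1 when adjusted over the list alone). The 3 with the smallest p act in mitotic chromosomes or on sister chromatids. The condensin subunit genes Ncaph and Ncapg2 fell from 21.9 ± 4.76 to 5.33 ± 0.73 FPKM and from 13.97 ± 2.58 to 3.37 ± 0.57 FPKM, and Esco2, a cohesin acetyltransferase gene, fell from 10.996 ± 2.57 to 2.33 ± 0.45 FPKM. The list passed camera (adjusted p = 0.0031), not with an estimated correlation (adjusted p = 0.42) and not without WT library 0 (adjusted p = 0.051).

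Effector genes went both ways. Of 30 measured effector and cytotoxic genes, 11 were higher and 5 lower (11 and 6 when adjusted over the list alone), and the list did not pass camera (adjusted p = 0.051). It passed without WT library 1 (adjusted p = 0.011) and without DKO library 0 (adjusted p = 0.015), with median-ratio scaling (adjusted p = 0.04975) and with fry (adjusted p = 0.011), but not with an estimated correlation (adjusted p = 0.58). It also passed in 2 settings chosen after the data were seen, without small RNA rows (adjusted p = 0.035) and with a term for Y-linked RNA (adjusted p = 0.025). Besides Gzma and Fasl, Itgae, the integrin chain CD103, rose from 62.4 ± 12.1 to 304 ± 28.4 FPKM. Of 25 listed genes of CD4 and helper lineages, 9 passed the filter and 16 did not. Of the 9, 5 were higher and 0 lower, also when adjusted over the list alone. The filter takes the mean over both groups, and St8sia6, for example, passed it only through its level in DKO. Gata3, a helper lineage factor, rose from 13.3 ± 0.079 to 42.8 ± 5.98 FPKM. That list passed camera (adjusted p = 9.6e-05), not with an estimated correlation (adjusted p = 0.41). Of 16 listed inhibitory receptor genes, 8 passed the filter and 8 did not. Of the 8 that passed, 4 were higher and 1 lower (4 and 2 when adjusted over the list alone). Among them Entpd1 (CD39) rose from 0.95 ± 0.17 to 6.26 ± 1.03 FPKM, and also passed the filter only through its level in DKO. Ctla4 rose from 12.8 ± 1.10 to 26.5 ± 2.18 FPKM. The inhibitory receptor list did not pass camera (adjusted p = 0.16), also not with an estimated correlation (adjusted p = 0.42). It passed without members that lists share (adjusted p = 0.029) and with fry (adjusted p = 0.0038). Beside these groups, Klri2, Fcgr3 and Zbtb16, markers of NK and innate lymphocytes, lay below the filter and were not tested. They stood at 0.051 ± 0.033, 0.071 ± 0.030 and 0.061 ± 0.029 FPKM in WT and at 0.64 ± 0.11, 0.44 ± 0.37 and 0.29 ± 0.11 FPKM in DKO (SD, n = 3), with no overlap between the groups. They were 3 of 12 such markers. Of all genes tested with limma, which lie above the filter, 34.1% also did not overlap.

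Naive, memory and homeostasis genes were lower more often than higher. Of 29 measured members 9 were lower and 2 higher (11 and 6 when adjusted over the list alone). Besides Dapl1, Actn1 fell from 70.7 ± 8.31 to 15.5 ± 1.01 FPKM, and Ccr7, the receptor for homing to lymph nodes, from 296 ± 27.1 to 133 ± 10.4 FPKM. The list passed camera (adjusted p = 0.044), not with an estimated correlation (adjusted p = 0.57) and not without WT library 0, WT library 2 or DKO library 0, where the adjusted p was 0.18, 0.077 and 0.094, nor without WT library 0 and DKO library 2 together (adjusted p = 0.083) or with a term for them (adjusted p = 0.098). Its medians per library overlapped between the groups, with WT library 1 at -0.056, below DKO libraries 1 and 2 at -0.0099 and 0.018 (log2, relative to the mean of the 6 libraries).

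Of the metabolic lists, glycolysis held the most called genes. Of 30 cholesterol and fatty acid synthesis genes 4 were higher and 0 lower (6 and 1 when adjusted over the list alone). Of 44 ribosome biogenesis and Myc target genes 4 were lower and 0 higher, also when adjusted over the list alone, and Rrp12 fell from 42.8 ± 0.79 to 27.8 ± 1.52 FPKM. Of 25 amino acid and ATF4 target genes 3 were lower and 0 higher (5 and 0 when adjusted over the list alone). Mthfd2, a mitochondrial folate enzyme gene, fell from 34.0 ± 1.17 to 9.78 ± 0.77 FPKM. Of 44 respiratory chain genes 1 was lower (0 when adjusted over the list alone). These 4 lists passed camera (adjusted p = 0.014, 0.00013, 0.0017 and 9.6e-05), and none did with an estimated correlation (adjusted p = 0.41, 0.42, 0.42 and 0.70). The respiratory chain list did not pass fry (adjusted p = 0.28), and its medians per library overlapped between the groups, with WT library 0 at -0.13, below DKO libraries 0 and 1 at -0.036 and -0.020. The lowest library of each group was WT library 0 and DKO library 2 (-0.40), which deviated from their groups together. The cholesterol list lost its call without WT library 0 (adjusted p = 0.065) or WT library 2 (adjusted p = 0.055), and without WT library 0 and DKO library 2 together (adjusted p = 0.071). Of 22 glycolysis genes 6 were lower and 1 higher (11 and 2 when adjusted over the list alone), and that list did not pass camera (adjusted p = 0.11).

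Other lists did not pass camera. Among them the adhesion, apoptosis and CDK inhibitor lists passed fry in the upward direction (adjusted p = 0.0064, 0.042 and 0.042), which tests whether the genes of a list move on balance one way and does not compare them with other genes. Of 29 genes of common gamma chain cytokine signalling, the pathway of IL-7 and IL-15, 4 were higher and 1 lower (4 and 2 when adjusted over the list alone). Cish, a feedback inhibitor of STAT5, rose from 17.7 ± 2.50 to 53.98 ± 7.16 FPKM. Of 25 adhesion and migration genes 7 were higher and 3 lower (9 and 5 when adjusted over the list alone). Of 21 apoptosis genes 3 were higher and 1 lower (4 and 1 when adjusted over the list alone), and of 16 CDK inhibitor and quiescence genes 2 were higher and 2 lower (3 and 2 when adjusted over the list alone). Of 18 immediate early genes 1 was higher and 1 lower (4 and 3 when adjusted over the list alone), and of 14 Wnt pathway genes 0 were higher and 1 lower (1 and 2 when adjusted over the list alone). Among 33 interferon-stimulated genes 1 was higher, also when adjusted over the list alone, and Slfn5 rose from 2.79 ± 0.57 to 23.7 ± 0.36 FPKM. The interferon list passed without DKO library 0 (adjusted p = 0.00082). Its members had an estimated correlation of 0.66, with which its camera adjusted p over all libraries was 0.92. The cytokine, apoptosis and interferon lists had medians just below 0 (-0.043, -0.043 and -0.0069) and means above 0 (0.059, 0.22 and 0.11), and camera gave the upward direction.

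**Figure D2:**
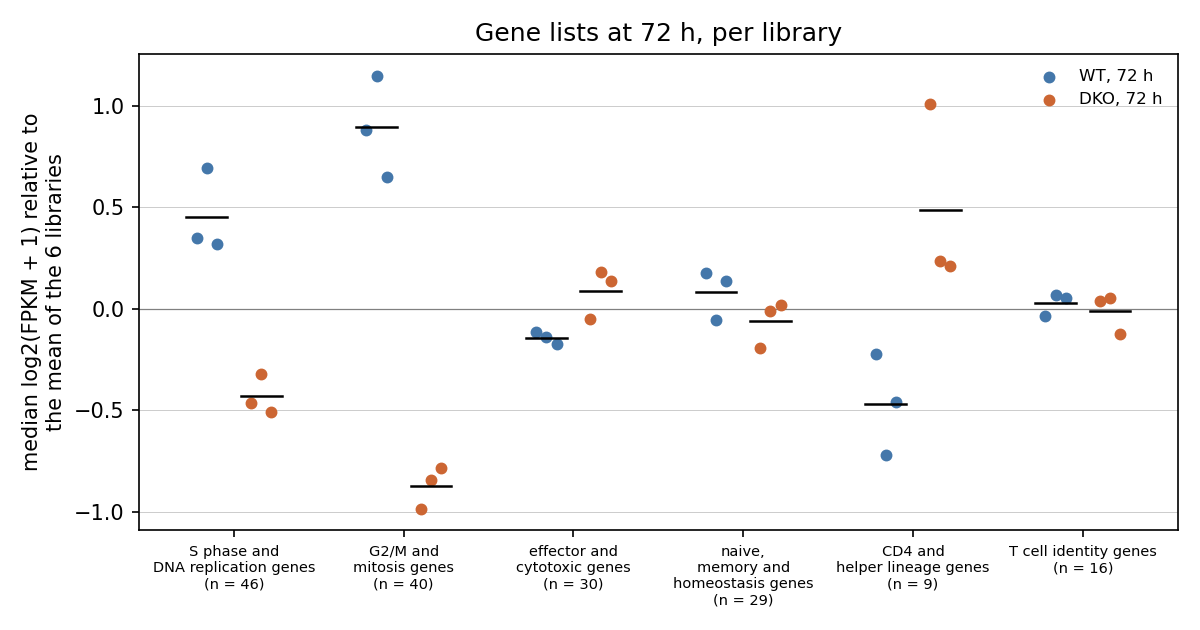
Median over the members of 6 gene lists of log2(FPKM + 1), relative to the mean of the 6 libraries, in WT (blue) and DKO (orange) cells at 72 h; points are libraries, bars group means and n the number of measured members. The groups lie apart for the S phase (n = 46), G2/M (n = 40), effector (n = 30) and CD4 and helper (n = 9) lists. They overlap for the naive, memory and homeostasis (n = 29) and T cell identity (n = 16) lists.

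Few marker genes of T cells or other cells were called by limma. Of 16 T cell identity genes 0 were called in either direction by limma, also when adjusted over the list alone. The 3 at an unadjusted p under 0.05 had groups that did not overlap. Cd3d and Zap70 were lower (log2 fold changes of -0.57 and -0.25) and Trat1 higher (0.76). Each gained a limma call in 1 alternative setting. The list passed the fry test for changes in mixed directions (adjusted p = 0.0026), which 19 of the 22 tested lists passed. Cd8a, which falls outside the rule for named genes, stood at 620 ± 5.60 FPKM in WT and 614 ± 58.3 FPKM in DKO. Of 6 measured myeloid markers 0 were called by limma (1 at an unadjusted p under 0.05), as was the single measured B cell marker (0 at that p), also when adjusted over each list alone. The member at that p was Tyrobp, which is also on the NK cell list and stood at 2.97 ± 1.53 FPKM in WT and 7.11 ± 3.32 FPKM in DKO (SD, n = 3; limma adjusted p = 0.17). Lyz2 stood at 1.82 ± 2.15 FPKM in WT and 0.54 ± 0.45 FPKM in DKO. The authors' deposited table calls Tyrobp higher (log2 fold change of 1.26, q = 0.011) and Lyz2 lower (-1.76, q = 0.011) in DKO at 72 h. The log2 fold change of Tyrobp was 1.06 and called (limma adjusted p = 0.016) with a term for Y-linked RNA, which was chosen after the data were seen. Of 3 measured NK cell markers Cd7, which T cells also express, was higher in DKO (301 ± 44.4 and 541 ± 76.5 FPKM, adjusted p = 0.030), also when adjusted over the list alone. That call was lost without WT library 0 or 2 (adjusted p = 0.071 and 0.088) or DKO library 0, 1 or 2 (0.10, 0.11 and 0.052), and of 14 erythroid and platelet markers 0 were measured above the filter. Of 12 NK and innate markers below the filter 3 were higher in DKO with no overlap between the groups and 0 lower. Chance gives 10% in either direction. Of 13 such B cell markers 1 was higher and 1 lower, and of 20 myeloid and 13 erythroid and platelet markers 0 were either. Among all genes tested with limma, which lie above the filter, 34.1% did not overlap between the groups. That share was not computed for all genes below the filter, so whether the 3 of 12 set NK markers apart cannot be told. The libraries differed in sex-linked RNA. Of 5 measured Y-linked and X inactivation genes 0 were called by limma, also when adjusted over the list alone, with 0 at an unadjusted p under 0.05. The authors' deposited table calls Xist lower in DKO at 72 h (log2 fold change of -1.11, q = 0.0012). Xist, made by the inactive X, stood at 55.01, 69.6 and 1.69 FPKM in WT libraries 0, 1 and 2 and at 56.9, 1.46 and 0.017 FPKM in DKO libraries 0, 1 and 2, and WT library 0 also held 15.6 FPKM of the Y-linked gene Ddx3y.

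The second comparison sets the genotype effect before culture against that at 72 h, from the authors' deposited table alone. That table calls 313 genes higher and 259 lower in DKO than WT cells at 0 h. Of these, 97 were called higher and 98 lower again at 72 h, where independent lists would share 5.01 and 9.82 of 11185 genes (Fisher's exact test across genes, two-sided, p = 9.4e-107 and 7.0e-74). No library is shared by these comparisons. Gzma (log2 fold change of 7.19 at 0 h in the authors' deposited table), Foxp3 (7.02) and Fasl (6.92) were already called higher at 0 h, and Dapl1 (-4.47) and Myb (-5.83) lower. Tcf7 was at -0.10 and not called (q = 0.53), and Lef1 was at -1.51, at 0 h in the authors' deposited table. Xist was at -8.96 there and is among the genes called lower at both times, so the 0 h groups also differed in X-inactivation RNA. Genes are not independent replicates, and the difference between time points was not tested per gene.

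The third comparison asks how WT and DKO cells changed from 0 h to 72 h, again from the authors' deposited table. It calls 954 genes up and 493 down in WT cells, and 618 up and 428 down in DKO cells. Up calls shared 461 genes and down calls 249, where independent lists would share 52.9 and 18.5 of 11145 genes. This counts 488 down calls in WT and 422 in DKO, since 0 h levels of genes with an infinite fall were left out. Genes called up in WT had a median log2 response of 1.74 in WT and 1.09 in DKO in the authors' deposited table, and genes called down had medians of -1.48 and -1.11. Picking genes by their WT call alone makes the WT response look larger. Genes called up in DKO had medians of 1.53 in DKO and 1.83 in WT, and genes called down in DKO had medians of -1.44 in DKO and -1.32 in WT. Across genes called in WT, the slope of the DKO on the WT response was 0.59 for up and 1.01 for down calls. Across genes called in DKO it was 0.40 and 0.63, so the slope depends on which genotype's calls pick the genes. G2/M genes were called up for 37 members in WT and 27 in DKO (median log2 of 4.202 and 2.21), and S phase genes for 40 and 22 members (medians of 1.93 and 0.99). Of 26 listed immediate early and TCR signal genes, the authors' deposited table calls 21 down in WT and 18 in DKO, with Fos at -10.02 and -10.83. It calls 1 up in each, Ier3, at 2.07 in WT and 1.31 in DKO. Xist was at 8.78 in DKO, where it was called up, and at 0.96 in WT, where it was not, and Ddx3y was called down in both (-1.67 and -1.54), so the groups compared also differed in sex-linked RNA. The difference in response was not tested per gene.

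The fourth comparison asks how genes that respond in WT differ by genotype at 72 h. Of the 954 genes called up in WT in the authors' deposited table, 298 were called lower in DKO at 72 h, or 31.2% (95% Wilson interval 28.4% to 34.2% across genes), and 35 were called higher. Both comparisons use the WT 72 h libraries. Independent lists would share 36.6 genes with the lower calls and 15.4 with the higher calls. For the lower calls, simulated unchanged groups that share the WT 72 h libraries gave a mean of 19.5% and at most 22.01% in 100 draws. In these draws no gene was changed, and genes were picked by rank to the observed numbers of calls, with no fold or q threshold. The authors' calls had to pass both thresholds, so shared noise may weigh less in them, and 31.2% has no fitting simulated level. Of the 493 genes called down in WT, 488 entered here, since 0 h levels were not counted for genes with an infinite fall. Of the 488, 39 were called higher in DKO, or 8.0%, where the simulated mean was 14.2% and independent lists would share 7.90 genes. The lowest of 100 draws shared 46 genes, so the simulated level did not hold for repressed genes. Their share called higher was 12.8% without a fold threshold and 12.9% with limma calls, sizes for which no simulation was run. The controls could not be split with 3 libraries. Part of the excess over independent lists among induced genes may therefore come from the shared libraries, by an amount these draws do not give.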

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

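Tests without small RNA rows, without WT library 0 and DKO library 2, with a term for these libraries or for Y-linked RNA, without cell cycle genes, and of the parts of camera, were chosen after the data were seen. The count of 1144 genes (462 higher, 682 lower) stayed within 1.5 times under other pseudocounts, filters, scalings and priors. It was 379 (104 and 275) with a 2-fold threshold and 603 (179 and 424) in the authors' calls, which also ask for a 2-fold change and 1 FPKM. At their q under 0.05 alone 746 genes were higher and 1140 lower over all rows, so the lower count comes with those thresholds. Leaving out single libraries gave 388 to 765 genes (128 to 294 higher, 260 to 471 lower), with the lowest count without DKO library 1, from fewer samples. Without WT library 0 and DKO library 2 the count was 28 (12 and 16) at 2 libraries per group, 19 of them shared, and Tcf7 and Lef1 lost their calls, while the G2/M median was -1.78. With a term for those libraries it was 1904 (793 and 1111). That term was drawn from the same residuals it removes, so the larger count is no independent evidence. The replicate block gave 356 (111 and 245). Same-numbered columns correlated at -0.50, 0.36 and -0.26 in their deviations, and not every sample correlated best with its own number. These values give no support for pairing by number but cannot exclude it. WT library 0 and DKO library 2 correlated at 0.74, and such a shared deviation could mask a weaker pairing. If the numbers do pair samples, the count of 356 applies.

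With an estimated correlation 0 lists were called instead of 9, and the cell cycle lists (medians -1.73 and -0.88) lost their calls, with an adjusted p of 0.41. That setting also lowers the degrees of freedom from 10721 to 4. The lower degrees of freedom alone left 2 lists, S phase and G2/M (adjusted p = 0.0043 for each), and the estimated correlation alone left 0 (adjusted p = 0.090 and 0.071). Shared calls at q under 0.05 with no fold threshold were 1029 instead of 195 between time points and 3761 instead of 710 between genotypes, from the looser threshold. The share of WT-induced genes called lower was 27.33% without a fold threshold, 34.9% with limma calls and 27.25% without cell cycle genes, and that of repressed genes called higher was 12.8% and 12.9% in the first 2. Genes that passed no test changed sign. Fcer1g was at -0.038 with quantile normalization, -0.0089 without both libraries, and -0.24 to 0.31 without single libraries. Uty was at -0.070 without both libraries and -0.54 to 1.02 without single libraries, and Ddx3y at -1.11 to 1.86. A floor of 1 FPKM could not alter the authors' calls, which already meet it. With 3 libraries per group and this spread, the simulated test recovered 32% of independent genes at a log2 change of 0.5. Absolute depth is unknown, so its limits were not tested. Count models were not run because no counts were given.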

Other observations

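The tests of other splits, T cell identity genes and gene families, the term for Y-linked RNA, and the parts of camera, were chosen after the result was seen. The genes in this paragraph fall outside the rule for named genes and were chosen after their values were seen, so they do not show how other genes moved. Of the 30 measured effector and cytotoxic genes 11 were higher and 5 lower. Gzmb, another granzyme gene, rose from 91.9 ± 28.9 to 491 ± 69.0 FPKM, Prf1, which encodes perforin, from 12.2 ± 3.44 to 70.5 ± 10.3 FPKM, and the chemokine gene Ccl5 from 146 ± 60.7 to 848 ± 42.2 FPKM (SD, n = 3). Eomes, a T-box factor of effector and memory CD8+ T cells, fell from 65.9 ± 24.02 to 9.35 ± 4.51 FPKM (limma adjusted p = 0.018), and lost its call without WT library 0 or 1 (adjusted p = 0.057 and 0.055) or DKO library 1 (0.051). Mki67, a gene of dividing cells, fell from 43.9 ± 9.95 to 8.56 ± 1.77 FPKM.

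The lower level of S phase and G2/M genes in DKO cells was set against technical explanations. With quantile normalization the median log2 fold change of the G2/M list was -1.724, which argues against library scaling. Cells other than T cells that dilute T cells would lower T cell identity genes too, whose median was -0.031 (SE 0.079 over members, range -0.57 to 0.76). Most of these genes do not tell kinds of T cell apart, so a change in the kinds of T cell was not tested. Within the libraries free of Y-linked RNA the G2/M median was -2.14 and within those low in Xist -1.43, with 1 or 2 libraries per group, and a term for Y-linked RNA over all libraries left it at -1.72, which argues against unequal sex. Only 1 of 10 splits of the 6 libraries gave as many as 1144 called genes, and the highest other split gave 5. Still, 10 splits are too few for a share under 0.05. Every other split mixes WT and DKO libraries within its groups, so a genotype difference would itself widen their spread and lower the count. The count of 5 is therefore no level for data without such a difference. The labelled genotype stays open as a biological difference, and nothing here tested how it would act.

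List calls with the preset correlation deserve caution. The real split called 9 lists, and every other split called at least 3 and at most 7. The groups of every other split hold unequal numbers of WT and DKO libraries, so part of a genotype effect stays in them. These counts therefore do not separate false calls from a carried-over genotype effect. As many as 9 came from 1 of 10 splits, too few for a share under 0.05. Correlation between members of a list may contribute, since an estimated correlation left 0 lists at unchanged degrees of freedom, and lower degrees of freedom alone left 2.

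WT library 0 and DKO library 2 deviated from their groups together, with a correlation of 0.76 across 10286 genes matched to a transcript. Their shared deviation went with transcript length across genes (Spearman 0.52), yet the correlation was 0.705 after a length trend was removed and 0.744 after a GC trend, which argues against either as the whole cause. Ribosomal protein genes took 27.2% and 23.1% of FPKM in these libraries and 30.03% to 34.4% in the other 4. The labels give no batch, and no biological explanation was tested.

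Small RNA rows with extreme folds may reflect scatter in the estimates of short transcripts. Their median SD within groups was 18.53 times that of other rows of like mean level. Rows at 0 in 3 libraries and at a mean of at least 50 FPKM in the other 3 numbered 62 in the real split and up to 67 in the other 9, against 0 among other genes. Differences of Snord45c, Mir6946 and Mir1901 may therefore be of this kind.

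Families that seemed to stand out among the called genes were tested without the genes that prompted the idea. Neither family passed a test, and both ideas stay open. Of 42 other glycosyltransferase genes 3 were higher, a share 1.676 times that of other genes (Fisher's exact p = 0.43, two-sided). Of 14 other annexin, S100 and galectin genes 1 was lower, a share 1.129 times that of other genes (Fisher's exact p = 0.60, two-sided). With so few members that share of 7.14% has an exact binomial upper 95% bound of 33.9%, against 6.32% of other genes, so a larger share of falls is not excluded.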
